A study of Gallus gallus with 4 samples.

How the data were processed

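Gene expression was measured in whole ovaries and testes of 17-week-old chickens from inbred congenic lines of White Leghorn origin. Per the labels, total RNA of 16 animals (8 females and 8 males) was combined in equal amounts into 4 pools of 4 animals, and each pool was hybridised to 1 Affymetrix Chicken Genome Array, giving 2 ovary pools and 2 testis pools. The values the authors deposited are log2 expression values per probe set. GCRMA and MAS5 are named in the submitters' processing notes, with no role, order or version given in the sources used here. The range of the deposited log2 values and their near-equal quantiles across arrays are of the kind GCRMA gives, and no further normalization was applied in the main analysis. Per the series design, the authors checked all arrays with affyPLM.

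The table held 38535 probe sets. Of these, 153 control probe sets were left out and 38382 were tested, made up of 37693 chicken probe sets and 689 probe sets for other sequences. The platform annotation gave 1 gene symbol for 27166 chicken probe sets and several symbols for 177, which were left unnamed, while 11037 tested probe sets had no symbol listed. Of the single-gene probe sets, 26863 were matched to a gene table of assembly GRCg7b by gene number, 308 by symbol and 7 not at all. That table was used only for symbols, chromosomes and the order of neighbouring genes, because the build behind the array is not given in the sources used here. The 13008 genes with a symbol comprised 609 Z-linked, 17 W-linked and 12355 autosomal genes and 27 with no chromosome used. A gene with several probe sets (7334 genes) was represented by the probe set with the highest mean over all 4 arrays. Among 2558 genes with at least 2 probe sets called, 289 had probe sets called in both directions.

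Testis was compared with ovary by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 38382 probe sets and a threshold of 0.05. Differences are log2 testis minus ovary, so that positive values are higher in testis. The fit had 2 residual degrees of freedom and 0.741 prior degrees of freedom. The p-values measure only the spread between these pools, not between single animals, and the number of arrays limits the precision. With a pool left out, the residual spread comes from the pools of the other organ alone. Exact permutation of 2 against 2 pools cannot go below p = 0.333. A background level of log2 3.32, the 99th percentile of the probe sets for other sequences, was set after the data were examined. These 689 probe sets were recognised by their names alone, their identity is not given in the sources used here, and every lower bound on a fold rests on this level. Where an organ was at or below it in both pools, the difference is given as "at least N-fold", from the mean of the brighter organ against the background level.

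Before the data were examined, 28 gene lists were fixed. They covered sex determination and gonadal fate, W-linked genes, oocyte, granulosa cell, steroidogenesis, Sertoli cell, germ cell and spermatogonia, meiosis, piRNA pathway, spermatid and acrosome, axoneme and motile cilium, intraflagellar transport, mitotic cell cycle, extracellular matrix, smooth muscle, endothelium, leukocyte, erythrocyte, ovarian surface and epithelium, adrenal and chromaffin, kidney, oviduct egg white, nerve and glia, Hedgehog and WNT signalling, TGF-beta family, ribosomal protein, oxidative phosphorylation and cholesterol synthesis. The 27 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists. With a correlation estimated from the 4 arrays, none of the 27 passed. In that form camera takes its degrees of freedom from the 2 residual ones, so that it has little power here. The estimates ran from -0.075 (germ cell and spermatogonia) to 0.545 (steroidogenesis), and lists with estimates below the preset 0.01 failed too. A failure in that form thus cannot show whether correlation between members accounts for a list's result. Fry, which asks whether members move on balance one way and does not compare a list with other genes, passed 24. Named genes were chosen by a rule fixed at the same time. It took the 12 largest differences in each direction without placeholder names, all measured members of the sex determination and W-linked lists, up to 4 called members per direction in every other list, and the 6 largest called Z-linked genes per direction.

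Z-linked genes were compared with autosomal genes by the difference of medians (camera) and by Fisher's exact test, two-sided, of the shares of called genes, with Clopper-Pearson 95% intervals that cover counting error only. Genes are not independent replicates. The 5 Z comparisons were adjusted together. The alternatives tried were filters on dim probe sets, a variance trend, robust moderation, no moderation, quantile normalization, median centring, floors on low values, the pool number as a block, each pool left out in turn, stricter thresholds, the mean of the probe sets of a gene, other set tests and matching of autosomal genes on expression. Added after the data were examined were chicken probe sets alone, a floor at the background level, probe sets with a plain suffix, and genes above background on all 4 arrays.

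The fit was tested on simulated data made from the spread of all 38382 probe sets. With 200 changed probe sets from the brighter part of the array, 50 of each size, it called 0, 10, 23 and 38 of those shifted by 0.5, 1, 2 and 4 log2 units, and 1 of its 72 calls was unchanged. With 3000 changed probe sets of each size, drawn from all 38382, it called 67.9%, 84%, 94.6% and 99%, and 4.45% of its 10850 calls were unchanged. Of all probe sets tested, 14597 lay at or below background on all 4 arrays. The runs thus differ in the brightness of the changed probe sets as well as in their number. The percentages need not hold for probe sets above background. Camera called 0 of 27 lists with no change simulated, and 1, the shifted one, when a list was moved by 1 log2 unit. Genes were simulated as independent of each other, so this run cannot show how camera does with correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.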

Results

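The data were 4 arrays from 17-week-old chickens, with 2 pools of ovaries and 2 pools of testes of 4 animals each, and the comparison addressed which genes are expressed differently in the gonads of the sexes. Between 55.1% and 55.7% of probe sets per array lay above the background level. Pools of the same organ correlated across probe sets at r = 0.991 for ovary and 0.995 for testis, and pools of different organs at 0.825 to 0.834. Probe sets are not independent replicates.

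Testis and ovary differed in 13666 of 38382 probe sets, of which 6666 were higher in testis and 7000 in ovary (limma, adjusted p under 0.05). Among the 12 named genes with the largest measured log2 differences toward testis were TUBA8B, an alpha-tubulin gene, at least 2530-fold higher (adjusted p = 0.000304), and TPPP2, a tubulin-binding protein gene, at least 2490-fold (adjusted p = 0.00104). Ovary was at background for all 12, so that these folds are lower bounds and do not rank the genes. They hold for the brightest probe set of each gene, and 1 of 2 probe sets of KIF2B and 2 of 3 of SPACA9 were called. PLCZ1, which encodes the sperm phospholipase that starts egg activation, was at least 1750-fold higher (adjusted p = 0.000505). SPERT was at least 1640-fold higher, KIF2B 1590-fold, DNAJB8 1250-fold, SPACA9 1140-fold, ZC2HC1B 1130-fold, ACR, which encodes the acrosomal protease acrosin, 1070-fold, CKMT2 951-fold, DUSP21 908-fold and AKAP14 897-fold. Among the 12 largest toward ovary, most of them lower bounds too, were the steroid 5-beta-reductase gene AKR1D1, at least 1220-fold (adjusted p = 0.000304), and CYP19A1, which encodes the aromatase that makes oestrogens, at least 1030-fold (adjusted p = 0.00165). The oocyte growth factor gene GDF9 was at least 870-fold higher in ovary, BTG4 868-fold, the W-linked HINTW 852-fold, BRDT 496-fold, the zona pellucida gene ZP3L2 489-fold, KPNA7 403-fold and WNT4 257-fold. For GDF9 and for HINTW 1 of 2 probe sets was called. CHGA was 903-fold higher in ovary by its measured values. Its testis values (log2 3.755 and 3.433) lay just above the background level. They were below the highest probe set for other sequences on each testis array (3.817 and 3.883). SGK2 (-9.63) and ZP2 (-9.27) were higher in ovary with a testis pool at background. Differences of at least 4-fold were called for 3182 probe sets in testis and 3113 in ovary, and of at least 16-fold for 1139 and 1014. Above background in both pools of one organ and in neither pool of the other were 1152 testis-higher and 1049 ovary-higher probe sets. No probe set for other sequences was called by limma, and 6 of 689 had an unadjusted p under 0.05. Without testis pool 1 the counts fell to 4177 testis-higher and 3898 ovary-higher probe sets, and without testis pool 2 to 4053 and 3734. Of 6894 genes called, 2927 were called in the same direction with every pool left out in turn.

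Most of the listed genes of sex determination were higher in ovary. DMRT1, the Z-linked testis-determining transcription factor gene, was an exception, at log2 13.87 ± 0.076 in testis and 9.30 ± 0.063 in ovary (SD, n = 2 pools each), a difference of 4.56 (SE 0.062, limma adjusted p = 0.000719). Of the 7 probe sets of DMRT1, 2 were called higher in testis and 0 in ovary. SOX9, a Sertoli cell transcription factor gene, was higher in testis by 2.74 (SE 0.028, adjusted p = 0.000528). Its ovary values (log2 3.874 and 3.924) lay close to background, below the highest probe set for other sequences on each ovary array (3.895 and 3.971). FOXL2, the ovarian transcription factor gene, was at least 209-fold higher in ovary (adjusted p = 0.00513), EMX2 at least 67.7-fold (adjusted p = 0.000393), and NR0B1 and NR5A1 7.52-fold and 6.93-fold (adjusted p = 0.0014 and 0.00252). NR0B1 and NR5A1 are also expressed in the adrenal cortex, and the adrenal genes CYP21A1 (at least 138-fold, adjusted p = 0.00167) and MC2R (at least 59.2-fold, adjusted p = 0.00063) were higher in the same ovary pools. LHX9 was 4.54-fold higher in ovary (adjusted p = 0.0022). Of 18 measured members of the list, 2 were higher in testis, 12 in ovary and 4 did not pass, with 2 and 12 adjusted over the list alone. Its median difference was -1.89 (camera adjusted p = 0.0141; adjusted p = 0.248 with an estimated correlation). The list mixes genes of ovarian and of testis fate, so that its counts and median depend on how many of each were listed. AMH, the anti-Müllerian hormone gene, was brighter in ovary than in testis (-1.60, adjusted p = 0.0317), as was HEMGN (-4.49, adjusted p = 0.0125). Of the 4 probe sets of AMH, 1 was called higher in ovary and 0 in testis. Also higher in ovary were the oestrogen receptor genes ESR1 (at least 2.65-fold, adjusted p = 0.0048) and ESR2 (-0.23, adjusted p = 0.0269), and RSPO1 (at least 1.7-fold, adjusted p = 0.00769). SOX8 (-0.53, adjusted p = 0.362), GATA4 (-1.17, adjusted p = 0.178), PTGDS (0.63, adjusted p = 0.338) and TOX3 (-0.20, adjusted p = 0.738) did not pass. The calls of AMH and HEMGN ended without ovary pool 2 (adjusted p = 0.116 and 0.0582) and without ovary pool 1 (0.1 and 0.0556), that of AMH also without testis pool 2 (0.0638). Those of RSPO1 and ESR1 ended without testis pool 1 (adjusted p = 0.0946 and 0.0723) and without testis pool 2 (0.0896 and 0.0751), and that of ESR2 with any single pool left out (0.0697 to 0.16).

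**Figure D1:**
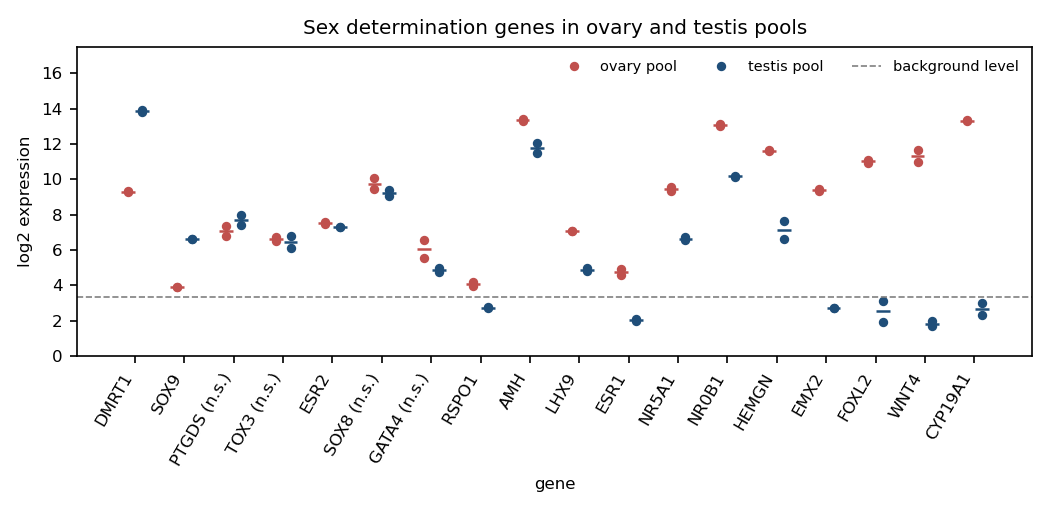
Log2 expression of the 18 measured sex determination genes, with a point per pool (2 ovary, 2 testis), a bar at each organ's mean and a dashed line at the background level of log2 3.32. Genes are ordered by measured log2 testis minus ovary from DMRT1 (4.56) to CYP19A1 (-10.69), and n.s. marks genes that did not pass the test.

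W-linked genes, carried by females alone, were mostly higher in ovary. HINTW stood at log2 13.06 ± 0.16 in ovary and 2.90 ± 0.22 in testis (SD, n = 2 pools each; limma adjusted p = 0.000884). The W copy of CHD1, listed as LOC374195, was at least 27.5-fold higher in ovary (adjusted p = 0.0015), and SPIN1L at least 29.7-fold (adjusted p = 0.00823). UBAP2L2 had a difference of 1.02 and did not pass (adjusted p = 0.417), while 1 of its 5 probe sets was called higher in ovary. Its difference was 1.69 without ovary pool 1 (adjusted p = 0.171) and 0.35 without ovary pool 2 (adjusted p = 0.844). Of the 4 measured members of the W-linked list, 3 were higher in ovary, 0 in testis and 1 did not pass, with 3 ovary-higher adjusted over the list alone, and the list was too short for camera. Among all 17 genes placed on W, chosen after the values were seen, 11 were higher in ovary, 10 of them with testis at background, and 0 in testis. The call of SPIN1L ended without testis pool 1 (adjusted p = 0.102) and without testis pool 2 (0.1). Probe sets of W-linked genes with a near-identical copy elsewhere can measure both, and whether those of MBD2 (0.65, adjusted p = 0.319) and NEDD4L (-0.11, adjusted p = 0.372), among the 6 genes that did not pass, measure the copies placed on W was not tested.

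Oocyte genes formed the group with the lowest median. GDF9 stood at log2 13.09 ± 0.038 in ovary and 2.35 ± 0.14 in testis (SD, n = 2 pools each; limma adjusted p = 0.000476). BTG4, KPNA7 and ZP2 were called in the same direction (adjusted p = 0.000798, 0.000655 and 0.00106). Of 18 oocyte genes, 16 were higher in ovary and 0 in testis, with 17 and 0 adjusted over the list alone (median -5.60, camera adjusted p = 1.96e-06; adjusted p = 0.248 with an estimated correlation). Granulosa cell genes divided. CYP19A1, FOXL2, IGFBP2 (9.43-fold, adjusted p = 0.00315) and HSD17B1 (at least 20.9-fold, adjusted p = 0.00357) were higher in ovary. The inhibin subunit genes INHBB (63-fold, adjusted p = 0.00119) and INHA (at least 7.4-fold, adjusted p = 0.00919) and the nuclear receptor gene NR5A2 (at least 11-fold, adjusted p = 0.00203) were higher in testis. For INHA and for NR5A2 1 of 2 probe sets was called, and for INHBB 2 of 2. Of 18 members, 9 were higher in ovary and 3 in testis, with 11 and 3 adjusted over the list alone. Camera did not call the list (median -1.36, camera adjusted p = 0.12; adjusted p = 0.375 with an estimated correlation). In steroidogenesis, CYP11A1, which encodes the side-chain cleavage enzyme, was 10.3-fold higher in ovary (adjusted p = 0.0102), as was POR (12-fold, adjusted p = 0.031). HSD17B4 (7.9-fold, adjusted p = 0.000753), the androgen-forming HSD17B3 (3.38, with an ovary pool at background, adjusted p = 0.0126), SRD5A2 (at least 7.13-fold, adjusted p = 0.0145) and FDX1 (1.65-fold, adjusted p = 0.0156) were higher in testis. Of 18 members, 10 were higher in ovary and 4 in testis, with 12 and 4 adjusted over the list alone. As a group they did not pass (median -1.76, camera adjusted p = 0.118; adjusted p = 0.752 with an estimated correlation). The adrenal steroid 21-hydroxylase gene CYP21A1 was at least 138-fold higher in the same ovary pools (adjusted p = 0.00167). The calls of INHA, HSD17B1 and HSD17B3 ended without testis pool 1 (adjusted p = 0.0816, 0.0608 and 0.112) and without testis pool 2 (0.0725, 0.0635 and 0.0972). Those of SRD5A2 and FDX1 ended without ovary pool 1 (0.0637 and 0.0672) and without ovary pool 2 (0.0639 and 0.0725), and that of POR with any single pool left out (0.0783 to 0.12).

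Genes of meiosis, the piRNA pathway and sperm formation were higher in testis. Among meiotic genes HORMAD1 and SYCP3, which encode parts of the chromosome axis, were 408-fold and 194-fold higher (limma adjusted p = 0.00252 and 0.00193), MEI1 was at least 125-fold higher (adjusted p = 0.000996) and TEX12, with an ovary pool at background, was higher by 8.54 (adjusted p = 0.00299). BRDT, a bromodomain gene of the list, was at least 496-fold higher in ovary instead (adjusted p = 0.000505). Of 26 meiotic genes, 17 were higher in testis and 1 in ovary, both over all probe sets and adjusted over the list alone (median 2.84, camera adjusted p = 1.71e-06; adjusted p = 0.248 with an estimated correlation). In the piRNA pathway, which silences transposons, TDRKH was at least 16.2-fold higher in testis (adjusted p = 0.00189) and PNLDC1 16.7-fold (adjusted p = 0.000541), with MOV10L1 at 26.1-fold (adjusted p = 0.00316). HENMT1 (-0.51, adjusted p = 0.0226) and TDRD5 (-0.21, adjusted p = 0.0447) were higher in ovary. Of 17 members, 14 were higher in testis and 2 in ovary, with 15 and 2 adjusted over the list alone (median 2.40, camera adjusted p = 3.88e-05; adjusted p = 0.248 with an estimated correlation). Spermatid and acrosome genes had the highest median of the lists, 5.90, with TSSK6, a spermiogenesis kinase gene, at least 740-fold higher (adjusted p = 0.000355). Of 25 members, 18 were higher in testis and 2, SPATA20 (-1.42, adjusted p = 0.0239) and PGK2 (-0.42, adjusted p = 0.041), in ovary, with 19 and 2 adjusted over the list alone (camera adjusted p = 1.19e-06; adjusted p = 0.248 with an estimated correlation). PGK2 was bright in both organs (log2 13.11 in ovary and 12.68 in testis), so that its probe set did not mark spermatids here. Without testis pool 2 adjusted p was 0.0501 for TEX12, 0.0589 for MOV10L1 and 0.134 for HENMT1, and without testis pool 1 it was 0.0587 for MOV10L1 and 0.161 for HENMT1. Without ovary pool 1 it was 0.0914 for SPATA20, 0.149 for PGK2 and 0.181 for TDRD5, and without ovary pool 2 it was 0.0937, 0.125 and 0.132, with HENMT1 at 0.0559. PGK2 and TDRD5 were at 0.0599 and 0.109 without testis pool 1, and at 0.0863 and 0.146 without testis pool 2.

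Genes of the sperm tail followed. TEKT5 and TEKT3, which encode tektins of the axonemal doublets, were at least 576-fold and 340-fold higher in testis (limma adjusted p = 0.000575 and 0.000542). CFAP206 was at least 331-fold (adjusted p = 0.000509) and the radial spoke gene RSPH9 471-fold higher (adjusted p = 0.000573). Of 60 axoneme and motile cilium genes, 52 were higher in testis and 2 in ovary, with 53 and 2 adjusted over the list alone (median 5.58, camera adjusted p = 1.83e-16; adjusted p = 0.248 with an estimated correlation). The ovary-higher members were CFAP221 (-3.64, adjusted p = 0.00252) and AK7 (-0.16, adjusted p = 0.0476). Among intraflagellar transport genes, which build cilia, TRAF3IP1 was 19.5-fold (adjusted p = 0.0134), IFT27 15.9-fold (adjusted p = 0.00369), WDR35 14-fold (adjusted p = 0.00472) and BBS7 13.3-fold (adjusted p = 0.00363) higher in testis. Of 34 members, 27 were higher in testis and 1, BBS9 (-1.03, adjusted p = 0.0461), in ovary, with 29 and 2 adjusted over the list alone (median 2.24, camera adjusted p = 1.13e-08; adjusted p = 0.248 with an estimated correlation). Other probe sets of BBS9 (2 of 3) were called in the opposite direction. Without testis pool 1 adjusted p was 0.111 for TRAF3IP1, 0.0638 for BBS7, 0.258 for BBS9 and 0.14 for AK7. Without testis pool 2 it was 0.122, 0.0649, 0.219 and 0.168, with IFT27 at 0.0524 and WDR35 at 0.0503. AK7 was at 0.146 without ovary pool 1 and 0.218 without ovary pool 2.

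Germ cell, Sertoli cell and mitotic genes went in both directions. STRA8, which marks entry into meiosis, was at least 156-fold higher in testis (limma adjusted p = 0.00198), PIWIL1 5.72-fold (adjusted p = 0.000728) and the germ cell helicase gene DDX4 25.9-fold (adjusted p = 0.00571). GFRA1 was 14.3-fold (adjusted p = 0.00369) and ID4 9.08-fold (adjusted p = 0.00975) higher in ovary, as was SALL4, with a testis pool at background (-7.67, adjusted p = 0.00434). Of 14 germ cell and spermatogonial genes, 5 were higher in testis and 6 in ovary, with 6 and 7 adjusted over the list alone. This list did not pass (camera adjusted p = 0.861; adjusted p = 0.894 with an estimated correlation). Its median was -0.10, while its mean was 0.20 and camera's direction was testis. Of 15 Sertoli cell genes, 6 were higher in testis, among them the tight junction gene CLDN11 (52.4-fold, adjusted p = 0.000341), and 3 in ovary, with 7 and 3 adjusted over the list alone. The 3 were AMH (1 of its 4 probe sets called), the follicle-stimulating hormone receptor gene FSHR (2.43-fold, adjusted p = 0.0273) and TJP1 (2.33-fold, adjusted p = 0.00671). The Sertoli cell list did not pass (camera adjusted p = 0.305; adjusted p = 0.512 with an estimated correlation), with a median of -0.05, a mean of 0.83 and camera's direction testis. Among mitotic genes TOP2A (15.6-fold, adjusted p = 0.00249) and PRC1 (9.67-fold, adjusted p = 0.00271) were higher in testis. GMNN (8.8-fold, adjusted p = 0.000915), KIF23 (5.86-fold, adjusted p = 0.00236) and CCNB1 (3.72-fold, adjusted p = 0.0035) were higher in ovary. Of 43 members, 10 were higher in testis and 13 in ovary, with 10 and 14 adjusted over the list alone. Camera did not call the list (median 0.02, camera adjusted p = 0.637; adjusted p = 0.894 with an estimated correlation). Without testis pool 1 adjusted p was 0.0815 for DDX4, 0.115 for FSHR and 0.0554 for TJP1, and without testis pool 2 it was 0.0791, 0.143 and 0.063. FSHR was at 0.0554 without ovary pool 1 and 0.0786 without ovary pool 2. AMH, called at 0.0317, was at 0.116 without ovary pool 2, 0.1 without ovary pool 1 and 0.0638 without testis pool 2.

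**Figure D2:**
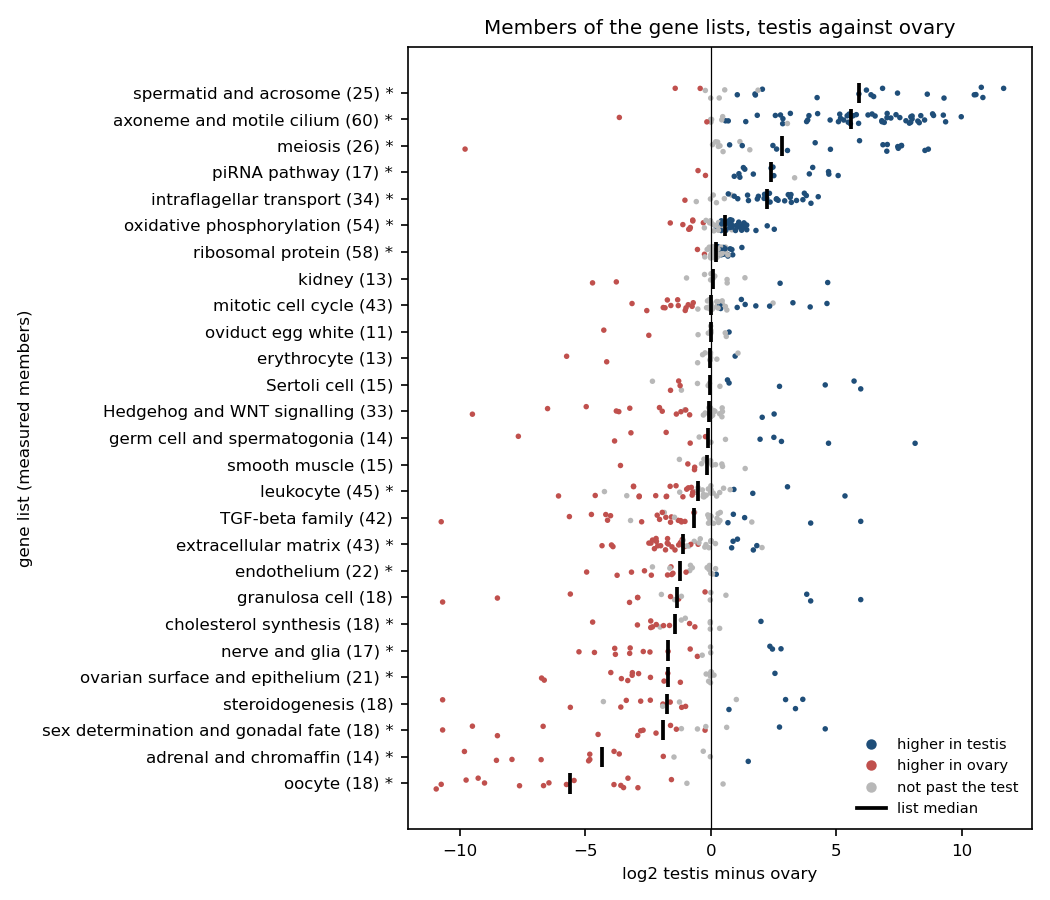
Log2 testis minus ovary of each measured member (points, blue higher in testis, red higher in ovary, grey not past the test) and the median (black bar) of the 27 lists tested, with the number of members in brackets. Asterisks mark the 16 lists that passed camera with the preset correlation, from spermatid and acrosome (median 5.90) to oocyte (-5.60); 0 passed with an estimated correlation, and the ribosomal protein and nerve and glia lists did not pass after quantile normalization.

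Lists of matrix, vessel and epithelial genes were higher in ovary. Among extracellular matrix genes COL12A1 was 20.2-fold (limma adjusted p = 0.00443) and the proteoglycan gene BGN at least 7.66-fold (adjusted p = 0.00076) higher in ovary. The basement membrane collagen gene COL4A1 was 2.09-fold higher in testis (adjusted p = 0.0051). Of 43 matrix genes, 24 were higher in ovary and 5 in testis, with 27 and 5 adjusted over the list alone (median -1.10, camera adjusted p = 0.00161; adjusted p = 0.248 with an estimated correlation). The endothelial genes EGFL7 (13.3-fold, adjusted p = 0.0033), SOX17 (8.94-fold, adjusted p = 0.00193) and EMCN (at least 21.1-fold, adjusted p = 0.00358) were higher in ovary. Of 22 endothelial genes, 10 were higher in ovary and 1, PECAM1 (0.22, adjusted p = 0.0276), in testis, with 13 and 1 adjusted over the list alone (median -1.25, camera adjusted p = 0.0141; adjusted p = 0.248 with an estimated correlation). In the ovarian surface and epithelium list the tight junction gene CLDN1 (107-fold, adjusted p = 0.00598), the splicing factor gene ESRP2 (at least 78.2-fold, adjusted p = 0.00293) and EPCAM (-3.98, adjusted p = 0.00125) were higher in ovary. In all, 12 of 21 members were higher in ovary and 1, MUC16 (at least 4.25-fold, adjusted p = 0.0146), in testis, both over all probe sets and adjusted over the list alone. This list had a median of -1.71 (camera adjusted p = 0.0102; adjusted p = 0.248 with an estimated correlation). With plain-suffix probe sets alone, an alternative added after the data were examined, its median was -0.18 and its adjusted p 0.0578. Of 15 smooth muscle genes, 4 were higher in ovary, led by SYNM (12.1-fold, adjusted p = 0.000949), and 0 in testis, with 2 and 0 adjusted over the list alone. As a group they did not pass (median -0.16, camera adjusted p = 0.465; adjusted p = 0.862 with an estimated correlation). PECAM1 and MUC16 lost their calls without testis pool 1 (adjusted p = 0.161 and 0.136) and without testis pool 2 (0.141 and 0.121), and PECAM1 also without ovary pools 1 and 2 (0.116 and 0.0796).

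Leukocyte genes were on balance higher in ovary, with the chemokine receptor gene CXCR4 at least 34.1-fold (limma adjusted p = 0.000341), IL7R at least 11.9-fold (adjusted p = 0.0019) and the macrophage receptor gene CSF1R 8.45-fold higher (adjusted p = 0.00712). Higher in testis were the phagocyte oxidase gene CYBB (at least 25.7-fold, adjusted p = 0.00286), IKZF1 (at least 4.22-fold, adjusted p = 0.00158) and the general leukocyte genes LCP1 (3.19-fold, adjusted p = 0.016) and PTPRC (1.89-fold, adjusted p = 0.0432). Of 45 members, 18 were higher in ovary and 4 in testis, with 19 and 4 adjusted over the list alone (median -0.51, camera adjusted p = 0.029; adjusted p = 0.375 with an estimated correlation). The leukocyte list's adjusted p was 0.0985 without testis pool 2 and 0.0605 with plain-suffix probe sets alone. Of 13 erythrocyte genes, the haemoglobin genes HBA1 (53.6-fold, adjusted p = 0.0141) and HBAD (17.7-fold, adjusted p = 0.0197) were higher in ovary. EPB41 was higher in testis (1.96-fold, adjusted p = 0.0315), with the same counts of 2 and 1 adjusted over the list alone. This list did not pass (median -0.02, camera adjusted p = 0.812, and 0.894 with an estimated correlation). Its median level was log2 2.78 in ovary and 3.03 in testis, both below the background level, so the test says little about erythrocyte genes. Without testis pool 1 adjusted p was 0.0512 for CYBB, 0.121 for LCP1 and 0.147 for PTPRC, and without testis pool 2 it was 0.0502, 0.102 and 0.182. PTPRC was at 0.0702 without ovary pool 1 and 0.111 without ovary pool 2. The log2 difference of HBAD was -4.15 with all pools, -3.55 without ovary pool 1 and -4.75 without ovary pool 2. HBA1 and HBAD lost their calls without testis pool 1 (adjusted p = 0.0839 and 0.165) and without testis pool 2 (0.0997 and 0.155), and EPB41 without ovary pool 1 (0.103), ovary pool 2 (0.117) and testis pool 2 (0.0566).

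Adrenal and nerve genes were bright in the ovary pools. CHGA, which encodes the secretory granule protein chromogranin A, stood at log2 13.41 ± 0.16 in ovary and 3.59 ± 0.23 in testis (SD, n = 2 pools each; limma adjusted p = 0.000932). TH, which encodes the rate-limiting enzyme of catecholamine synthesis, was at least 108-fold higher in ovary (adjusted p = 0.0049), and the corticotropin receptor gene MC2R at least 59.2-fold (adjusted p = 0.00063). Of 14 adrenal and chromaffin genes, 10 were higher in ovary and 1, NPY (2.82-fold, adjusted p = 0.0357), in testis, with the same counts adjusted over the list alone (median -4.34, camera adjusted p = 0.00161; adjusted p = 0.488 with an estimated correlation). The neurofilament genes NEFM (38.1-fold, adjusted p = 0.000304) and NEFL (13.9-fold, adjusted p = 0.00321) were higher in ovary, and S100B (6.96-fold, adjusted p = 0.00774) and ELAVL4 (5.49-fold, adjusted p = 0.0025) in testis. Of 17 nerve and glia genes, 11 were higher in ovary and 3 in testis, with the same counts adjusted over the list alone (median -1.70, camera adjusted p = 0.0428; adjusted p = 0.375 with an estimated correlation). The nerve and glia list did not pass without testis pool 1 (adjusted p = 0.0657) or without testis pool 2 (0.0861). Nor did it pass after quantile normalization (adjusted p = 0.0553), after median centring (0.0519), with the mean of the probe sets of a gene (0.0541) or without the dimmer probe sets (0.146). With the mean of the probe sets its median was -0.78. Among kidney genes SLC3A1 (25.3-fold, adjusted p = 0.000579) and UMOD (6.79-fold, adjusted p = 0.000705) were higher in testis. PODXL (13.6-fold, adjusted p = 0.00386) and AQP3 were higher in ovary, so that each organ had 2 of 13 members, also adjusted over the list alone. Camera did not call the list (median 0.11, camera adjusted p = 0.548; adjusted p = 0.752 with an estimated correlation). Of 11 egg white genes of the oviduct, OVSTL (at least 8.36-fold, adjusted p = 0.0115) and OVAL (at least 2.31-fold, adjusted p = 0.0088), the ovalbumin gene, were higher in ovary. TF was higher in testis (1.66-fold, adjusted p = 0.00232), with the same counts adjusted over the list alone. As a group they did not pass (median 0, mean -0.49, camera's direction ovary, adjusted p = 0.972, and 0.974 with an estimated correlation). The median level of the egg white list was log2 2.87 in ovary and 2.86 in testis, both below the background level, so the test says little about it. Other probe sets of TF (2 of 4) were called in the opposite direction. Without testis pool 1 adjusted p was 0.0759 for TH, 0.229 for NPY, 0.122 for OVSTL and 0.106 for OVAL, and without testis pool 2 it was 0.0767, 0.19, 0.12 and 0.104.

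Among signalling genes WNT6 was at least 53-fold (limma adjusted p = 0.00445), RSPO3 31.2-fold (adjusted p = 0.00196) and the WNT antagonist gene SFRP1 13.6-fold (adjusted p = 0.00326) higher in ovary. WNT5A was 5.76-fold (adjusted p = 0.0045) and the Hedgehog receptor gene PTCH1 4.14-fold (adjusted p = 0.0303) higher in testis. Of 33 Hedgehog and WNT genes, 12 were higher in ovary and 2 in testis, with the same counts adjusted over the list alone. This list did not pass (median -0.06, camera adjusted p = 0.156; adjusted p = 0.375 with an estimated correlation). In the TGF-beta family TGFB2 (27-fold, adjusted p = 0.00218) and BMP2 (18.2-fold, adjusted p = 0.000796) were higher in ovary and INHBB in testis. Of 42 members, 18 were higher in ovary and 5 in testis, with 20 and 6 adjusted over the list alone. Camera did not call the list (median -0.66, camera adjusted p = 0.107; adjusted p = 0.364 with an estimated correlation). PTCH1 lost its call with any single pool left out (adjusted p = 0.0776 to 0.118), and WNT5A without testis pool 2 (0.0518).

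Ribosomal and respiratory chain genes were slightly higher in testis and cholesterol synthesis genes higher in ovary. RPL35A was 2.36-fold (limma adjusted p = 0.00202) and the Z-linked RPL17 1.79-fold (adjusted p = 0.00724) higher in testis. Of 58 ribosomal protein genes, 16 were higher in testis and 2 in ovary, with 14 and 2 adjusted over the list alone (median 0.19, camera adjusted p = 0.000479; adjusted p = 0.561 with an estimated correlation). After quantile normalization the ribosomal median was 0.07 and the list did not pass (adjusted p = 0.111). NDUFB4, a subunit gene of complex I, was 2.70-fold higher in testis (adjusted p = 0.00529), and NDUFA5 and the cytochrome c gene CYCS were 3.06-fold and 2.16-fold higher in ovary (adjusted p = 0.00261 and 0.00378). Of 54 oxidative phosphorylation genes, 31 were higher in testis and 8 in ovary, with 34 and 8 adjusted over the list alone (median 0.55, camera adjusted p = 0.000333; adjusted p = 0.375 with an estimated correlation). With plain-suffix probe sets alone the list's median was 0.12 and its adjusted p 0.0528. In cholesterol synthesis HSD17B7 (26.1-fold, adjusted p = 0.000957), NSDHL (7.59-fold, adjusted p = 0.000374) and the lanosterol synthase gene LSS (5.25-fold, adjusted p = 0.00715) were higher in ovary. Of 18 members, 10 were higher in ovary and 1, STARD4 (4-fold, adjusted p = 0.00115), in testis, with 11 and 1 adjusted over the list alone (median -1.41, camera adjusted p = 0.0141; adjusted p = 0.248 with an estimated correlation).

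Males carry a pair of Z chromosomes and females a single Z, and Z-linked genes lay toward testis. TPPP2 and CKMT2, the mitochondrial creatine kinase gene, were at least 2490-fold and 951-fold higher in testis (limma adjusted p = 0.00104 and 0.000334). Other Z-linked genes higher in testis were the aquaglyceroporin gene AQP7 (at least 392-fold, adjusted p = 0.000304), C9orf24 (at least 304-fold, adjusted p = 0.000304), LOC427161 (at least 200-fold, adjusted p = 0.00153) and GOLM1 (203-fold, adjusted p = 0.00231). MCTP1 (181-fold, adjusted p = 0.000739), DAB2 (at least 143-fold, adjusted p = 0.000304), CRHBP (-5.89, with a testis pool at background, adjusted p = 0.00319), IL7R (at least 11.9-fold, adjusted p = 0.0019) and AQP3 (at least 9.76-fold, adjusted p = 0.000531) were Z-linked and higher in ovary, as was HEMGN (22.5-fold, adjusted p = 0.0125, and 0.0556 and 0.0582 without ovary pools 1 and 2). The median of the 609 Z-linked genes was 0.39 and that of 12355 autosomal genes -0.02, a difference of 0.41 or 1.33-fold (camera adjusted p = 8.7e-05 over 5 comparisons; p = 0.169 with an estimated correlation). Among genes above background on all 4 arrays, the difference was 0.71 or 1.63-fold, over 445 Z-linked and 8636 autosomal genes (p = 0.172 with an estimated correlation). Over all genes with plain-suffix probe sets alone, the difference was 0.205. Higher in testis were 252 Z-linked genes, 41.4% (95% interval 37.4 to 45.4), against 23.5% of autosomal genes (odds ratio 2.3, Fisher's exact test, adjusted p = 1.27e-20). Higher in ovary were 101 Z-linked genes, 16.6% (13.7 to 19.8), against 29.3% (odds ratio 0.479, Fisher's exact test, adjusted p = 1.92e-12). At least 4-fold higher in testis were 20.7% of Z-linked and 10.4% of autosomal genes (Fisher's exact test, adjusted p = 1.18e-12), and at least 4-fold higher in ovary 6.24% and 12.1% (adjusted p = 3.15e-06). Tested 1 chromosome at a time, Z alone of 33 chromosomes passed camera (adjusted p = 0.0028; adjusted p = 0.989 with an estimated correlation). Chromosome 38, with 21 genes, had a higher median than Z (0.436 against 0.388) and did not pass (camera adjusted p = 0.254). Without testis pool 1 the testis-higher shares were 23% of Z-linked and 13.5% of autosomal genes and the ovary-higher shares 9.36% and 16.9%. Without testis pool 2 they were 22.7% and 13.4%, and 7.72% and 16%. The shares at least 4-fold higher in testis were 13.3% and 7.1% without testis pool 1, and 12.5% and 6.66% without testis pool 2.

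**Figure D3:**
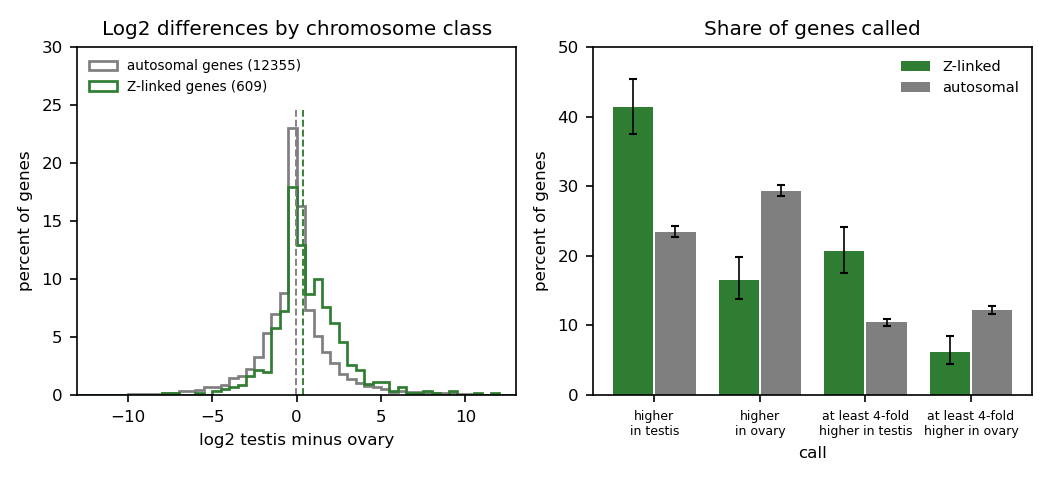
Left, the distribution of log2 testis minus ovary (percent of genes per bin) for 609 Z-linked (green) and 12355 autosomal genes (grey), with dashed lines at the medians of 0.39 and -0.02. Right, the percent of genes called in each direction, with 95% Clopper-Pearson intervals: 41.4% of Z-linked and 23.5% of autosomal genes were higher in testis.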

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

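Chosen only after the data were examined were the alternatives with chicken probe sets alone, the floor at the background level, plain-suffix probe sets, and genes above background on all 4 arrays. Testis-higher and ovary-higher probe sets numbered 6666 and 7000, and fell to 3993 and 4245 at an adjusted p under 0.01, to 3465 and 3582 when tested against a 2-fold bound, and to 4284 and 4570 with no moderation. Leaving out each pool in turn gave 4053 to 6007 testis-higher and 3734 to 6449 ovary-higher probe sets, lowest without testis pool 2; each such fit rests on 3 arrays, and the lone pool is assumed to vary like the other organ's. With the pool number as a replicate block, the counts were 5506 and 5874. Pools of the same number did not deviate together over all probe sets (r = 0.052), so no shift shared by both organs was seen. A pairing with unlike effects in the organs cannot be seen this way. The 16 lists past camera became 0 with an estimated correlation, and the p of the Z-linked minus autosomal difference of 0.406 became 0.169. In that form both the estimate and the test rest on 2 residual degrees of freedom, so that a failure there decides little. That difference was 0.205 with plain-suffix probe sets alone, 0.581 without the dimmest 25% of probe sets and 0.885 without the dimmer 50%, so its size depends on the probe sets used. The share of Z-linked genes higher in testis ran from 22.7% without testis pool 2 to 55.8% without the dimmer 50%. With the mean of the probe sets of a gene, BBS9 (1.50), LAMA2 (-2.40) and TF (-1.29) turned direction, since their probe sets were called in both directions. Of values for named genes 2279 kept direction and call and 262 lost the call, most often with a testis pool left out. By design such a fit takes its residual spread from the ovary pools alone, so these losses do not point to the testis pools. The ovary pools lay over 1 log2 unit apart in 1405 probe sets and the testis pools in 725, with like median differences (0.070 and 0.071). Whether this spread accounts for all the losses was not tested. Genes at the background level in one organ have only a lower bound for their fold.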

Other observations

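The tests of symbol families, of the medullary and cortical adrenal genes, of the difference between the ovary pools and of the spread of the somatic lists were chosen only after the results they bear on had been seen. The tests on Z-linked genes were set after the shift of all Z-linked genes had been seen, but before the values given here.

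Sorting nexin, RAB and tetraspanin genes were on balance higher in ovary in a scan of 80 families of at least 15 genes with a shared symbol stem, of which 5 passed camera. Among sorting nexins, which sort endosomal cargo, SNX19 (-3.70, limma adjusted p = 0.00296) and SNX7 (-3.64, adjusted p = 0.0012) were higher in ovary, and 16 of 25 SNX genes were called there and 0 in testis (median -1.19, camera adjusted p = 0.0102; adjusted p = 0.957 with an estimated correlation). Of 58 RAB genes, which include small GTPases of vesicle transport, 32 were higher in ovary and 7 in testis (median -0.72, adjusted p = 0.0382; adjusted p = 0.957 with an estimated correlation), with RAB32 (-5.46, adjusted p = 0.00411) and RAB11FIP4 (5.98, adjusted p = 0.000855) at the ends. Of 17 tetraspanin genes, 11 were higher in ovary and 1, TSPAN17 (1.36, adjusted p = 0.0478), in testis (median -1.41, adjusted p = 0.0478; adjusted p = 0.957 with an estimated correlation). Other families with members in membrane traffic did not pass, among them AP (median -0.84, adjusted p = 0.061), VPS (-0.20, adjusted p = 0.781) and SEC (0.06, adjusted p = 0.724). The other families that passed were CFAP (median 3.82, adjusted p = 0.000805) and RPL (0.16, adjusted p = 0.014), with 14 of 22 and 34 of 40 genes already in the fixed lists and adjusted p = 0.957 for both with an estimated correlation.

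Adrenal and chromaffin genes were bright in both ovary pools. The cortical genes CYP21A1, MC2R and MRAP had a median difference of -6.76, which argues against nerve fibres and glia as the only source. The 6 medullary genes had a median of -4.85, but 5 of the 6 lay above background in both ovary pools and DBH in 1 alone, so that adrenal tissue in the pools is neither borne out nor excluded by them. All 12 members above background were higher in ovary pool 1 than in ovary pool 2, by a median of 0.27. The medians of 95% of random gene sets matched on ovary level lay between -0.188 and 0.102. But this sets 1 pool against 1 pool, and genes expressed together shift together whatever their source, so it cannot decide. Adrenal tissue in uneven amounts and expression of these genes by ovarian cells both stay open.

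Z-linked genes lay toward testis, and genes restricted to testis may account for part of the shift. As a description alone, the Z-linked minus autosomal median was 0.406 over all genes. It was 0.835 where the mean of a gene over both organs lay above background (514 Z-linked and 9863 autosomal genes). That filter keeps genes bright in 1 organ alone. Among genes above background on all 4 arrays, the Z-linked minus autosomal median was 0.708 (0.649 to 0.713 for single testis pools against single ovary pools; p = 0.172 with an estimated correlation), which argues against genes silent in ovary as the only cause. The lower quartile was also higher, by 0.675 (bootstrap SE 0.111), as a double dose of Z in males would give, and as any broad shift would. The upper quartile was higher by 0.958. The difference of medians stayed below the 1 log2 unit of 2 copies against 1. Differences between neighbouring Z-linked genes showed a rank correlation of 0.02 (95% of shuffled orders lay between -0.081 and 0.077), with no sign of regional control along the whole chromosome. Medians of windows of 15 genes ran from -0.82 to 2.02. Of 2000 shuffled orders, 29% had as low a window and 58.2% as high a window. A short region with few measured genes could be missed by both. Organ and sex chromosome dose differ together in this design, so that other differences between ovary and testis stay open.

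Several lists of somatic cell genes were lower in testis, and a smaller somatic share of testis RNA could lower them all. With CLDN5, a member of 2 lists, counted as endothelial alone, the medians of 6 lists spread from -1.70 (nerve and glia) to 0.16 (Sertoli cell), or 1.86 log2 units, but Sertoli cells occur in testis alone, so that their list says nothing on this. Without it the range was 1.54 (as large in 3.48% of 10000 random reassignments of the genes), and without the nerve and glia list too it was 1.09 (9.32%). The outcome thus depends on which lists are included, and reassignments treat genes as independent, so that a smaller somatic share and differences in the makeup of the somatic cells both stay open.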
